A study of Mus musculus with 3 samples.

How the data were processed

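Peritoneal cells of 5 naive female BALB/c mice were pooled, stained and sorted by flow cytometry in a pair of successive rounds, per the labels' protocols. From each of 3 populations 100 cells were lysed, and whole-transcript cDNA was amplified, biotinylated and hybridised to 1 whole-transcript array. Mast cell progenitors, mature mast cells and type 2 innate lymphoid cells therefore have 1 array each. Amplification from so few cells can lose transcripts or change their proportions, and pooling removes the differences between mice, so neither source of error can be measured here.

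The values used are the deposited log2 expression levels of 41345 probe sets, made by the authors with RMA, per the submitters' processing notes, which name it without software or version. RMA in general corrects background, normalizes between arrays and summarises each probe set by median polish. The log2 scale was read from the values, which run from 2.23 to 13.7 as RMA output does, and the arrays' percentiles 1 to 99 differed by at most 0.413. Levels below a gene's detection limit are not marked in the table, and background signal sets a floor that shrinks differences of dim genes. Probe-level signals were not used here. The number of arrays limits the precision of each value.

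Probe sets were named with the platform's gene table. Of the probe sets, 23521 named 1 gene, 1814 named several genes and 16010 were unnamed in the table used. Entrez identifiers of 23328 of the single-gene probe sets matched the mouse RefSeq gene table of GRCm38.p6, which changed no symbol. That table was used for names only. No genome build is given in the sources used here, and no coordinates are printed. A gene was represented by its probe set with the highest mean over the 3 arrays, which gave 22180 genes, of which 1082 had several probe sets. Among genes past 4-fold that had several probe sets, at least 2 probe sets passed in 9 of 42 (progenitors and mature mast cells), 17 of 62 (progenitors and innate lymphoid cells) and 7 of 30 (mature mast and innate lymphoid cells).

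Differences of log2 levels were taken between each pair of arrays. With 1 array per population no test was possible. A gene was counted when the difference was at least 2 in size and its level in the brighter array was above that array's median over single-gene probe sets (6.32 for progenitors, 6.30 for mature mast cells and 6.30 for innate lymphoid cells). The size rule, this floor and 29 gene lists with 553 members were fixed before the data were examined, and 497 members were measured. Among list members not analysed here were Il1rl1, which encodes the sort marker ST2, Areg and Lyn. The lists cover sort markers, mast cell granule, mediator, receptor and transcription factor genes, progenitor and cell cycle genes, ribosomal, metabolic and lysosomal genes, innate lymphoid genes, response genes and markers of other peritoneal cells. For each list, the median difference was placed among 10000 random lists of the same size matched on mean level in 20 bins, and a list was taken to stand apart at or below percentile 2.5 or at or above 97.5. The 87 percentiles describe these arrays and are not p-values. The bins hold equal numbers of genes, so the brightest bin reaches below a log2 level of 8, since 693 genes had a mean of 8 or more. The spread of differences grows with level, with an SD of 0.56 at 7 to 8 and 1.16 above 9 between the mast cell populations. Percentiles of lists with bright members may therefore be too extreme. Since exact ties set the medians of the random lists to 0, a list median close to 0 can lie at an extreme percentile by construction. The mean difference was therefore placed in the same way. A mean can rest on few members, and some genes, such as Cd63 and Ccr2, belong to more than 1 list. Folds of genes whose dimmer level lies below that array's median are given as at least the fold over that median, or as levels where that bound is under 4-fold. Counts use the measured differences.

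Genes named in the text were drawn from a set given by a rule fixed in advance. For each comparison the rule took the 10 largest differences in each direction among genes past 4-fold, leaving out provisional gene names and symbols of microRNA and small nucleolar RNA genes (Mir and Snor), all sort markers, and up to 6 members of each list with the largest differences above the floor. Genes above both other populations, or shared by both mast cell populations, were taken by their smaller difference, up to 10 for each. Not every gene of this set is described, among them the small Cajal body RNA genes Scarna8 and Scarna17, and those described were picked with their values known. B2m and the genes of the closing paragraphs that lie outside this rule were chosen after their values were seen. The 1390 olfactory and vomeronasal receptor genes were chosen as a background after the data were examined.

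Alternatives fixed in advance were no floor, a floor at the 75th percentile, arrays set to one median, quantile normalization, removal of the trend with level (lowess, fraction 0.3), an offset of 32 on the linear scale, the mean over a gene's probe sets, genes with 1 probe set, list members above the floor only, and differences of 2-fold and 8-fold. A floor at the 95th percentile, protein-coding genes without olfactory and vomeronasal receptors, list means in place of medians, and levels below an array's median raised to it were added later. The size rule and the list placement were tested on simulated arrays of 22180 genes for each comparison. All of 100 genes with a log2 change of 3 were recovered and none of 100 with a change of 1 was called. Of 200 random lists 7%, 5% and 9% stood apart, in the order of comparisons given above. The noise was normal, without ties, with the spread of the dimmer 75% of genes. Changes of 3 and 1 lie on either side of the cut by construction. No unchanged gene was called, whereas 0.863% to 1.87% of receptor genes passed on the real arrays. The simulation thus checks the computation and not its error on these arrays. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.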

Results

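Transcript levels were measured in 3 cell populations sorted from the peritoneal cavity of female BALB/c mice, with 1 array per population. The populations were mast cell progenitors, mature mast cells and type 2 innate lymphoid cells, the last a lymphoid population that the study took as a distant relative of mast cells. Cells of 5 naive mice were pooled, and 100 sorted cells of each population were lysed and their RNA amplified. Both mast cell populations came from a gate for high c-kit and for FcεRI, the high-affinity IgE receptor. Progenitors had low side scatter and high integrin β7, and mature cells had high side scatter and lower integrin β7. There are no replicates, so no value has an error, no difference was tested and no p-value is given. A gene was counted when its log2 levels on a pair of arrays differed by at least 2, which is 4-fold, and its brighter array was above that array's median. Levels of 22180 genes were compared. Genes above a log2 level of 8 numbered 619 in progenitors, 788 in mature mast cells and 811 in innate lymphoid cells.

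Progenitors carried the granule protease transcripts Cpa3, Cma1 and Mcpt4 at high levels, within 3-fold of those in mature mast cells, whereas some genes of the IgE receptor, mediator synthesis and heparin synthesis were at least 4-fold lower. Cpa3, which encodes mast cell carboxypeptidase, was at a log2 level of 12.30 in progenitors and 12.83 in mature cells. The transcripts for Kit, the stem cell factor receptor, and Fcer1a, the IgE-binding chain of FcεRI, were 10.6-fold and at least 5.89-fold lower in progenitors, although both proteins were used to sort the cells. Where the dimmer level lies below its array's median, the fold is given as at least that over the median. In all, 25 genes were at least 4-fold higher and 185 at least 4-fold lower in progenitors than in mature mast cells. Genes of similar level in the other populations were also lower at times, by a comparison chosen after the data were examined. Of 489 genes above a log2 level of 8 and within 2-fold of each other on the other arrays, 10.2% were at least 4-fold lower in progenitors. The same share was 0% of 371 genes for mature mast cells and 1.24% of 402 for innate lymphoid cells.

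Of the 14 mast cell proteases, 2 were at least 4-fold lower in progenitors, none was higher and 12 did not reach 4-fold. The lower members were Cma2, a chymase-family gene, at 5.51 against 9.51, and the tryptase gene Tpsb2 at 8.94 against 11.74. Cma1 and Mcpt4, which encode chymases, were 2.54-fold and 2.78-fold lower. The median log2 difference of the list was -0.46, at percentile 0 of 10000 random lists of matched size and level, which describes these arrays alone, and the mean was -0.76, at percentile 0.18. Means were placed in the same way after the data were examined.

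Where genes for other granule contents reached 2-fold, they were lower in progenitors. Of 15 genes of the granule core and heparin synthesis, 1 was at least 4-fold lower, Ndst2, an enzyme of heparin sulfation, at 6.81 against 10.59. Srgn, which encodes the proteoglycan core serglycin, was at 8.13 against 9.20. Of 14 genes for amine and lipid mediators, 2 were at least 4-fold lower. These were Tph1, the rate-limiting enzyme of serotonin synthesis, at 5.86 against 9.57, and Hpgds, the haematopoietic prostaglandin D synthase, at 5.79 against 8.07. Hdc, the histamine-forming enzyme, was at 5.59 against 7.05. Of 26 lysosomal genes none reached 4-fold, and Psap, a precursor of lysosomal activator proteins, was 2.91-fold lower.

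Of 15 genes of the IgE receptor and its signalling, Fcer1a alone was at least 4-fold lower, and 6 were at least 2-fold lower. Ms4a2, the β chain of the receptor, was at 6.25 against 8.13, the kinase gene Btk at 5.94 against 7.51 and the adaptor gene Lat2 at 8.52 against 9.71. Among 21 receptors of connective tissue mast cells, Mrgprb1 was 7.41-fold lower, and 20 did not reach 2-fold. Mrgprb2, a receptor for cationic activators of mast cells, was at 8.06 against 8.16, and Cd63, a tetraspanin of granule membranes, at 10.29 against 10.54. Of the 7 measured sort markers, Kit and Fcer1a were at least 4-fold lower in progenitors. By their means, the lists of mediators (-0.66, percentile 0.07), the IgE receptor (-0.75, 0.04) and sort markers (percentile 0.33) stood apart as well, although their medians were 0. The transcript of Itgb7, the integrin chain that separated the populations by protein, was at 7.60 in progenitors and 7.82 in mature cells.

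Few listed genes of immature cells were counted as different between the mast cell populations, but most were dim or exactly tied, so small differences would not be seen. Tied members numbered 9 of 16 mast cell transcription factors, 13 of 19 stem and progenitor genes and 20 of 23 genes of mitosis, and above a log2 level of 8 these lists had 0, 1 and 0 members. None of 16 mast cell transcription factors reached 2-fold, with Gata2 at 7.59 in both and Gata1 at 6.43 against 6.54. None of 19 stem and progenitor genes was at least 4-fold different. Cd34, a surface protein of haematopoietic progenitors, was at 7.85 against 7.82, and Myb, a progenitor transcription factor, was lower in progenitors at 6.38 against 8.21, by its brighter probe set alone. None of 11 granulocyte-monocyte progenitor genes reached 2-fold. Of 21 genes of DNA replication 1 was at least 4-fold lower, the primase gene Prim1 at 6.10 against 8.20. None of 23 genes of mitosis reached 2-fold, including the proliferation marker Mki67 at 6.39 in both populations.

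Some broadly expressed genes were also lower in progenitors. Of 33 cytosolic ribosomal protein genes, 3 were at least 4-fold lower, Rpl38 (7.46 against 10.95), Rps4x (6.81 against 9.30) and Rpl28 (8.16 against 10.33), and none was 4-fold higher. The ribosomal list did not stand apart, with a median of 0 and a mean of -0.35, at percentile 9.11 for the mean. Of 30 genes of oxidative phosphorylation 2 were at least 4-fold lower. These were the respiratory chain genes Ndufa1 at 6.09 against 9.23 and Cycs at 5.71 against 9.17, although the 5 probe sets of Cycs disagreed. The list's median difference was -0.03 and its mean -0.43, at percentile 1.10 for the mean. None of 13 glycolytic genes reached 4-fold, with a median difference of -0.07 and a mean of -0.18, at percentile 12.6 for the mean. Exact ties set the random medians to 0, which puts medians this small at extreme percentiles, so their placement is not given. B2m, the light chain of MHC class I, was at 7.54 in progenitors, 12.11 in mature cells and 12.08 in innate lymphoid cells.

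The 10 genes with the largest differences in favour of progenitors included 5 olfactory receptor genes, led by Olfr772 at 11.48 against 6.30. The others included Ptma, which encodes prothymosin α, at 10.54 against 7.69, Commd6 at 11.08 against 8.28 and Fabp6, a bile acid binding protein gene, at 9.75 against 5.67. The 10 with the largest differences in favour of mature cells included 3 olfactory receptor genes, led by Olfr339 at 10.52 against 3.31. Brk1, a component of the actin-regulating WAVE complex, was at 10.74 against 5.65, and Sec61g, a subunit of the protein translocation channel, at 10.86 against 6.02. Olfactory and vomeronasal receptor genes, known mainly from sensory neurons, give a measure of how often a gene passes the size rule in these arrays. Of 1390 such genes, 26 (1.87%) were at least 4-fold different between the mast cell populations, 7 higher and 19 lower in progenitors, against 184 of 20790 other genes (0.885%), 18 higher and 166 lower. With the floor at the 95th percentile the shares were 1.08% and 0.803%. Over all levels, other genes thus passed no more often than this background. Passing the size rule therefore does not by itself mark a difference between the populations. The receptor and other genes were not matched on level, and passing depended on level. Of 229 genes with a mean level of 9 or more, receptors included, 1 was at least 4-fold higher and 22 lower in progenitors. Of 9961 genes at 6 to 7, 7 were higher and 38 lower. Whether bright genes passed more often than receptor genes of like level was not tested.

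**Figure D1:**
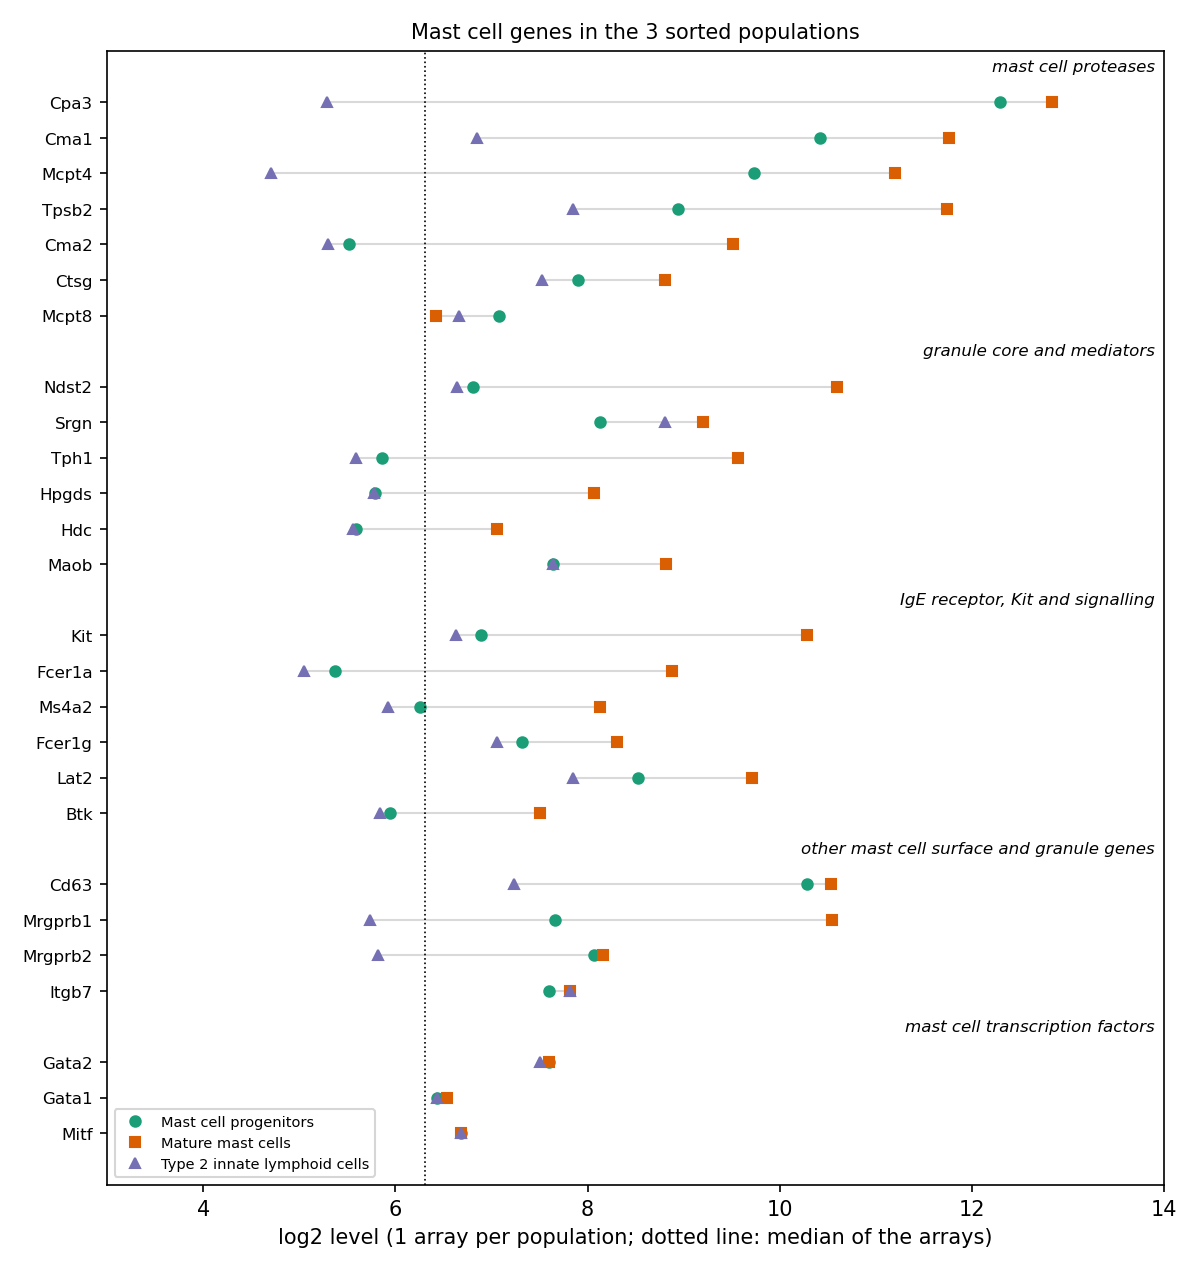
Log2 level (x axis) of mast cell genes in progenitors (circles), mature mast cells (squares) and type 2 innate lymphoid cells (triangles), 1 array each, with a dotted line at the mean of the array medians; coincident markers hide one another. Cpa3 was near 12.30 and 12.83 in the mast cell populations, whereas Kit in progenitors (6.88) lay near the innate lymphoid level (6.63).

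Progenitors were compared with type 2 innate lymphoid cells to set them against a distantly related population of the same cavity. Granule protease genes were among those higher in progenitors, and some lymphoid surface and ribosomal protein genes among those lower. Cpa3 was at least 63.7-fold higher in progenitors, Mcpt4 at least 10.7-fold and Cma1 11.9-fold. Ctla2a, a cysteine protease inhibitor gene, was at least 33.3-fold lower. Fabp5, a fatty acid binding protein gene, was at least 17.8-fold lower by the brightest of its 4 probe sets. In all, 46 genes were at least 4-fold higher and 197 at least 4-fold lower in progenitors.

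Of the 14 proteases 3 were at least 4-fold higher in progenitors (Cpa3, Mcpt4 and Cma1) and none was lower. The list's median difference was 0.31, at percentile 99.99, and its mean 1.32, at percentile 100. Of 21 connective tissue mast cell receptors 2 were at least 4-fold higher, Cd63 (8.29-fold) and Mrgprb2 (8.06 against 5.82). Cd63 was also the only member of the lysosomal list to reach 4-fold. The signalling adaptor gene Tyrobp was 8.78-fold higher. None of the IgE receptor genes, the heparin genes or the mediator genes reached 2-fold in this comparison. Fcer1a was at 5.37 in progenitors and 5.05 in innate lymphoid cells, Kit at 6.88 and 6.63, Ndst2 at 6.81 and 6.64, and Tph1 at 5.86 and 5.59. None of the mast cell transcription factors or of the stem cell, granulocyte-monocyte or cell cycle lists reached 2-fold either. Most members of each of these lists were exactly tied, so small differences would not be seen.

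Of 23 surface receptors of type 2 innate lymphoid cells, 3 were at least 4-fold lower in progenitors. They were Il7r, the interleukin 7 receptor chain CD127 used in the sort (5.89 against 8.72), Klrg1, an inhibitory receptor (6.05 against 8.11), and Tnfrsf18, the receptor GITR (7.38 against 9.41). Il2ra, which encodes the sort marker CD25, was at 6.58 against 7.25. Among 30 integrins and homing receptors 2 were at least 4-fold lower, the chemokine receptor genes Ccr2 (5.82 against 9.50) and Cxcr6 (6.03 against 9.41). Of 20 type 2 cytokines and effectors Arg1, which encodes arginase 1, was 6.02-fold lower and no other reached 2-fold. None of 17 transcription factors of these lymphoid cells reached 2-fold, but 10 were exactly tied and 0 were above a log2 level of 8. Id2, required for innate lymphoid development, was at 6.86 against 7.81 and Gata3 at 6.76 against 6.82.

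Of 33 ribosomal protein genes 9 were at least 4-fold lower in progenitors and 1 was higher. The median difference was -0.38, at percentile 0, and the mean -0.92, at percentile 0.03. Rpl38 was 17.2-fold lower and Rpl14 11-fold lower, whereas Rplp0 was 7.06-fold higher by its brighter probe set. Of 30 genes of oxidative phosphorylation 5 were at least 4-fold lower, among them Ndufa1 (at least 21.6-fold), Cox5a (7.42-fold) and Cox4i1 (7.08-fold). Of the olfactory and vomeronasal receptor genes 12 (0.863%) passed the size rule here, 7 higher and 5 lower in progenitors, against 231 of the other genes (1.11%), 39 higher and 192 lower. By their means, connective tissue mast cell receptors (0.33, percentile 99.6), oxidative phosphorylation (-0.61, 0.33), integrins and homing receptors (-0.41, 0.41) and innate lymphoid surface receptors (-0.35, 0.1) stood apart in this comparison, with medians of 0.

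Mature mast cells were compared with the same innate lymphoid cells. Genes for proteases, mediator synthesis, heparin synthesis, the IgE receptor and surface receptors were among those higher in mature cells. Cpa3 was at least 92.3-fold, Mcpt4 at least 29.8-fold and Cma1 30.2-fold higher, and the sort markers Kit and Fcer1a were 12.6-fold and at least 5.94-fold higher. In all, 127 genes were at least 4-fold higher and 89 at least 4-fold lower in mature mast cells.

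Of the 14 proteases 5 were at least 4-fold higher in mature cells, the further members being Cma2 (at least 9.22-fold) and Tpsb2 (14.8-fold). The median difference was 0.70 and the mean 2.08, both at percentile 100. Of the 14 mediator genes 2 were at least 4-fold higher, Tph1 (at least 9.62-fold) and Hpgds (8.07 against 5.78), with a median difference of 0.04 and a mean of 0.71, the mean at percentile 100. Ndst2 was 15.5-fold higher and the only one of 15 heparin and granule core genes to reach 4-fold. In the IgE receptor list 2 of 15 genes reached 4-fold, Fcer1a and Ms4a2 (8.13 against 5.92), and 7 reached 2-fold. Among connective tissue mast cell receptors 3 of 21 were at least 4-fold higher, Mrgprb1 (at least 18.9-fold), Cd63 (9.85-fold) and Mrgprb2 (8.16 against 5.82). None of the 16 mast cell transcription factors reached 2-fold, but 9 were exactly tied and 1 was above a log2 level of 8. Gata2 was at 7.59 against 7.50, so differences of these genes may not be seen here.

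On the lymphoid side, Ctla2a was at least 33.7-fold lower in mature mast cells, Casp1, which encodes the inflammatory caspase 1, at least 15.4-fold lower and Emb, a cell adhesion gene, 22.8-fold lower by its brighter probe set. Of the 23 lymphoid surface genes 2 reached 4-fold, Il7r (at least 5.36-fold lower) and Klrg1 (5.87 against 8.11). Cxcr6 was at least 8.64-fold, Ccr2 at least 9.18-fold and Arg1 5.35-fold lower. No lymphoid transcription factor reached 2-fold, but 12 of 17 were exactly tied and 0 were above a log2 level of 8, so differences may not be seen. None of the 33 listed ribosomal protein genes was 4-fold different, but 10 were at least 2-fold lower in mature cells. The median difference was -0.59, at percentile 0, and the mean -0.57, at percentile 0.04. Of 30 genes of oxidative phosphorylation 2 were at least 4-fold lower, Cox5a (6.12-fold) and Cox4i1 (5.34-fold). Of the olfactory and vomeronasal receptor genes 23 (1.65%) passed the size rule, 20 higher and 3 lower in mature cells, against 193 of the other genes (0.928%), 107 higher and 86 lower. Here too the other genes passed no more often than this background over all levels, again without matching on level. By their means, with medians of 0, the lists of granule core and heparin genes (0.37, percentile 98.3), the IgE receptor (0.86, 100), connective tissue mast cell receptors (0.47, 99.9) and lysosomal genes (0.26, 99.4) stood apart as higher in mature cells. Integrins and homing receptors (-0.36, 0.16) and innate lymphoid surface receptors (-0.38, 0.02) did so as lower.

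**Figure D2:**
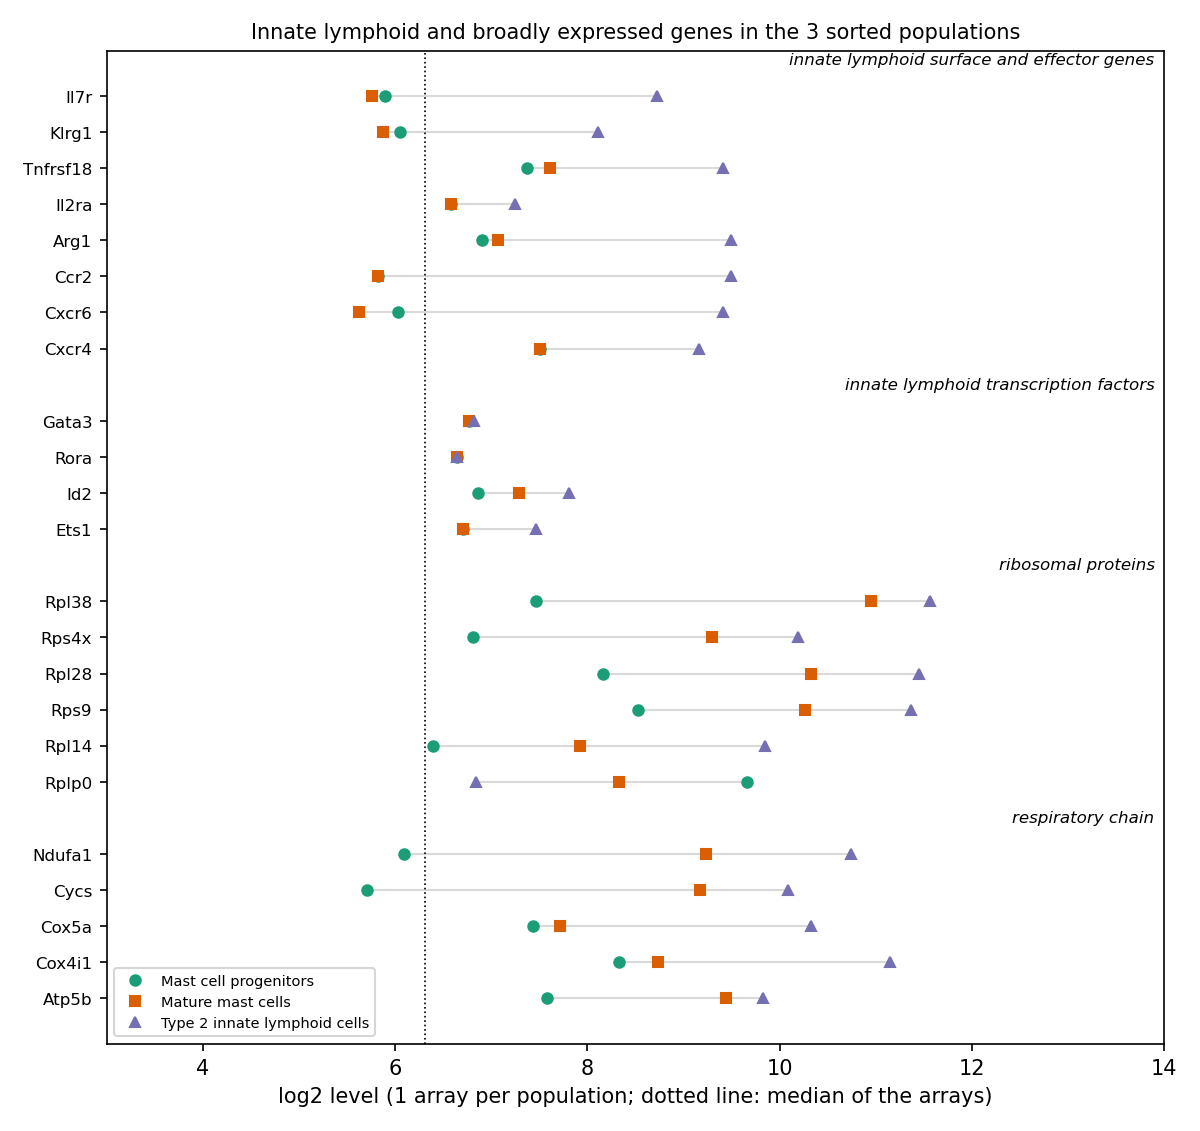
Log2 level (x axis) of innate lymphoid, ribosomal and respiratory chain genes in progenitors (circles), mature mast cells (squares) and type 2 innate lymphoid cells (triangles), 1 array each, with a dotted line at the mean of the array medians; coincident markers hide one another. Il7r was at 8.72 in innate lymphoid cells against 5.89 and 5.76 in the mast cell populations, and Rpl38 was lowest in progenitors (7.46).

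Across all 3 populations, 11 genes were at least 4-fold higher in both mast cell populations than in innate lymphoid cells. They included Cpa3, Mcpt4, Cma1, Tyrobp, Cd63, Mrgprb2, the dipeptidase gene Dpep2 and Aldh2, the mitochondrial aldehyde dehydrogenase gene (9.20 and 11.41 against 7.19). Genes at least 4-fold above both other populations numbered 21 in progenitors, 108 in mature mast cells and 82 in innate lymphoid cells. Cks2, which encodes a subunit that binds cyclin-dependent kinases, stood out in progenitors at 8.08 against 5.74 in mature cells and 4.80 in innate lymphoid cells. These levels are from the brightest of its 4 probe sets. Restricting the counts to 17615 protein-coding genes without olfactory and vomeronasal receptors, a choice made after the data were examined, gave 8, 70 and 64 genes.

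Few markers of other peritoneal cells reached 4-fold. No member of the lists for T and B lymphocytes, eosinophils and neutrophils, mesothelial cells with fibroblasts and dendritic cells, or NK cells with other innate lymphoid cells was 4-fold different in any comparison. The same held for MHC class II, interferon response, immediate early and Y-linked genes. Most of these genes were dim and many were tied, so this does not show that the sorts were free of other cells. Between the mast cell populations, 7 of 14 T and B lymphocyte markers and 10 of 17 eosinophil and neutrophil markers were exactly tied. Above a log2 level of 8 these lists had 1 and 0 members. The NK list had a median difference of -0.01 and a mean of -0.14 between mature mast cells and innate lymphoid cells, the mean at percentile 7.53. The macrophage and monocyte list stood apart there by its mean of -0.18 (percentile 2.01), with a median of 0. Ccr2 was its only member to reach 2-fold there, and 20 others did not. In the macrophage list only Ccr2, and in the basophil list only Lilrb4a (7.29 in progenitors against 9.92), reached 4-fold, both being higher in innate lymphoid cells.

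As whole profiles, the 3 arrays were about equally alike. Pearson's r across 22180 genes was 0.934 for progenitors with mature cells, 0.924 for progenitors with innate lymphoid cells and 0.931 for mature with innate lymphoid cells. Genes are not independent replicates. Spearman's rho was 0.951, 0.952 and 0.952. Over the 1141 genes above a log2 level of 8 on at least 1 array, r was 0.506, 0.416 and 0.368 in the same order. Over the 11938 genes above the median of at least 1 array, r was 0.744, 0.716 and 0.747, so which pair was closest depended on the genes used. Values were exactly equal on all 3 arrays for 10626 genes (47.9%), so a list median of 0 carries little information, and 79 of the 87 list medians lay within 0.01 of 0.

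**Figure D3:**
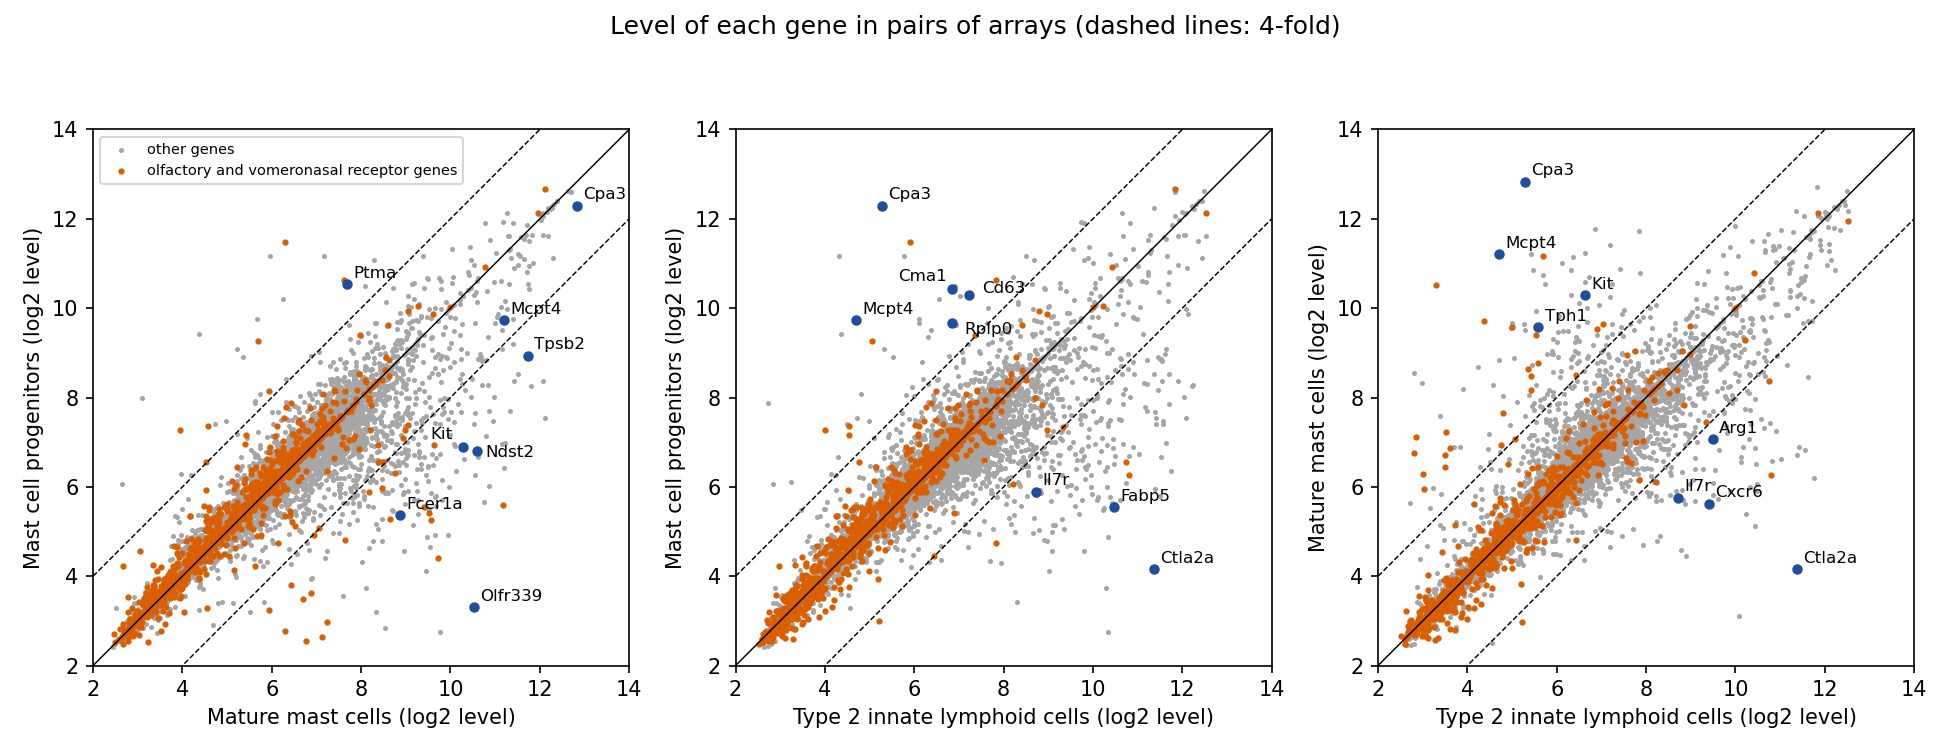
Log2 level of each of 22180 genes on 1 array (y axis) against another (x axis) for the 3 pairs of populations, with the line of equality, dashed lines at 4-fold olfactory and vomeronasal receptor genes in orange and named genes in blue. By the size rule, more genes lay below the lower dashed line than above the upper one for progenitors against mature cells (185 and 25) and against innate lymphoid cells (197 and 46).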

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

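Probe sets outside the gene comparisons carried differences as well. Of 1814 probe sets that name several genes, 36 were at least 4-fold different between progenitors and mature mast cells, 62 between progenitors and innate lymphoid cells and 51 between mature mast and innate lymphoid cells. Of 16010 probe sets with no gene in the table used, 727 (4.54%), 779 (4.87%) and 769 (4.80%) passed the same rule in that order. These shares were higher than the 0.885%, 1.11% and 0.928% found among genes other than olfactory and vomeronasal receptors. What the unnamed probe sets measure was not analysed here, and no explanation was tested for them.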

How the results depend on the processing

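Counts limited to protein-coding genes without olfactory and vomeronasal receptors, the floor at the 95th percentile, list means and levels raised to the array median were alternatives chosen after the data were examined. All 10 counts stayed within 1.5 times their value with no floor, floors at the 75th and 95th percentile, one median, quantile normalization, the trend removed, the mean over a gene's probe sets and genes with 1 probe set. Setting the arrays to one median could change little, since their medians were already 6.22, 6.21 and 6.20. Quantile normalization had more to change, since the arrays' percentiles 1 to 99 differed by up to 0.413, but this is small against the size rule of 2. Most genes have 1 probe set, so the settings for probe sets could change little too. The size rule moved all 10 counts by construction. In the order progenitors above and below mature cells, progenitors above and below innate lymphoid cells, mature cells above and below innate lymphoid cells, standing out in progenitors, mature cells and innate lymphoid cells, and shared by both mast populations, 2-fold gave 113, 428, 170, 417, 297, 280, 93, 240, 245 and 39 genes, and 8-fold gave 11, 81, 21, 94, 66, 39, 10, 44, 32 and 7. An offset of 32, which shrinks differences of dim genes by construction, left 15 genes higher in progenitors than in mature cells, 84 higher in mature than in innate lymphoid cells, 68 standing out in mature cells and 7 shared. Levels below an array's median raised to it left 15 genes higher in progenitors than in mature cells and kept the other 9 counts within 1.5 times their value. Protein-coding genes without receptors gave 8 and 24 genes higher in progenitors than in mature and innate lymphoid cells, 84 higher in mature than in innate lymphoid cells, and 8 and 70 standing out in progenitors and mature cells, by fewer genes. Pearson's r between the mast populations minus the highest other was -0.0045 with the floor at the 75th percentile, and for Spearman's rho it was -0.0128. For Pearson's r, the sign of this difference had turned already with the floor at the array median (0.744 against 0.747), but not above a log2 level of 8 (0.506 against 0.416). Of the lists that stood apart, the NK list no longer did after quantile normalization (median -0.0198) or by its mean (-0.142), glycolysis between the mast populations by the mean over probe sets (median 0) or by its mean (-0.178), and mediators between mature and innate lymphoid cells by the mean over probe sets or with genes of 1 probe set (median 0 in both); the cause was not tested. In 40 other cases a list came to stand apart under an alternative, such as the IgE receptor list between the mast populations by its mean (-0.753). Of the differences of named genes under the alternatives, 3390 stayed within 1 SD of the receptor genes' differences, used in place of a replicate spread, and 113 moved by more, none with a change of sign. Dim genes limit these results, since signal near the array median cannot be told from background.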

Other observations

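The tests of mixing with mature cells, of loss by abundance and of a scale difference between arrays were chosen after the results were seen, as were the genes named in this part. Innate lymphoid cells stood out in genes not covered by the lists. S100a4, a calcium-binding protein gene, was at a log2 level of 10.44 against 6.87 in both mast cell populations, Klf6, a zinc finger transcription factor gene, at 10.31 against 6.94 in progenitors and 7.07 in mature cells, and the interferon-inducible GTPase gene Gbp4 at 7.93 against 4.29 and 4.70. Rbpj, the DNA-binding partner of Notch, was at 10.78 against 8.63 and 7.43, and Cd52, a lymphocyte surface glycoprotein gene, at 8.55 against 6.34 in both.

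Mature mast cells also stood out in genes not covered by the lists, of which a few with known functions are given. The tetraspanin gene Cd81 was at 10.79 against 7.15 in progenitors and 7.86 in innate lymphoid cells, and Plek, which encodes pleckstrin, at 10.08 against 6.95 in both. Rgs18, a regulator of G protein signalling, was at 8.69 against 5.93 and 4.24, and Pik3cg, the catalytic subunit of phosphoinositide 3-kinase γ, at 8.47 against 6.17 and 6.07. Serpinb1a, an inhibitor of granule serine proteases, was at 10.71 in mature cells, 8.27 in progenitors and 6.73 in innate lymphoid cells.

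Many more genes were lower than higher on the progenitor array. Olfactory and vomeronasal receptor genes, taken as background, were also more often lower against mature cells (19 lower and 7 higher) but not against innate lymphoid cells (5 lower and 7 higher), and 20 were higher and 3 lower in mature than in innate lymphoid cells. Of 489 genes above a log2 level of 8 and within 2-fold of each other on the other arrays, 10.2% were at least 4-fold lower in progenitors, including B2m, the GTPase gene Rhoa (8.37 against 12.07 and 11.54) and Actg1, a cytoplasmic actin gene (8.31 against 10.26 and 11.22). The same share was 0% for mature mast cells and 1.24% for innate lymphoid cells. The median difference of the 489 genes from the mean of the other arrays was -0.0316 (SD across genes 1.19), and the arrays' percentiles 1 to 99 differed by at most 0.413. A scale difference or trend left in these values would move bright genes alike, and the median of -0.0316 shows no such shift. Removing the trend with level left 183 genes lower and 25 higher against mature cells, and 185 and 48 against innate lymphoid cells. The median difference was 0 at mean levels below 9, so this removal could change little and adds no support. By the median of the bright genes alone, whose bounds were set once it was known, a shift left in the normalized values is argued against as the whole cause. Normalization between arrays can itself remove such a shift, so a scale difference before it cannot be judged. Incomplete recovery of transcripts from the 100 progenitor cells may account for part of the lower genes. A lower RNA content or a true difference of progenitors stays open and was not tested.

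Progenitors combined bright Cpa3, Cma1 and Mcpt4 with Kit and Fcer1a near the innate lymphoid level. For the 14 genes of the mast cell lists at least 4-fold higher in mature than in innate lymphoid cells, the signal above the innate lymphoid level in progenitors was under 10% of that in mature cells for 8 and up to 91.6% for the others. Some of the low shares rest on levels below the array median. Mature mast cells in the progenitor sort as the whole cause could not be told apart from other explanations. No single share of mature cells placed all 14 genes within 2-fold. A share of 4% to 7% placed the most but left 5 of 14 above it by at least 2-fold. The share of 37% given by Cma1 left 8 below it. A share of 0% already left only 7 outside, so the test could hardly count against mixing. Of the 489 bright genes above, 24.1% also lay outside 2-fold in progenitors. Loss of the less abundant transcripts in the progenitor array might add to the pattern, but the part of the difference kept followed the mature level with a Spearman's rho of 0.411 across these genes, which lies between the bounds set for and against it. A real difference in the order in which progenitors express these genes stays open, and 1 array per population keeps all of these open.

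Exact ties between arrays were common, with 47.9% of genes equal on all 3 arrays, and less common above a log2 level of 8 (7.79%). Pure noise for 20 probes per set, summarised by median polish over 3 arrays, tied all 3 in 55.2% of simulated sets, against 16.7% for 10 probes and 77.6% for 30 probes. These ties are consistent with the summary step, and might hide small differences of dim genes. The number of probes per set on this array was not used here, and a biological explanation was not tested.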
